A study of Mus musculus with 8 samples.

How the data were processed

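Total RNA of whole kidneys was isolated with TRIzol, cleaned on RNeasy columns and labelled with biotin by the standard Affymetrix procedure, per the labels' protocols. Each of the 8 arrays held RNA of a separate female mouse of a mixed C57BL/6 and SV127 background, 4 labelled mutant and 4 labelled control. The values used were the authors' deposited table of 35556 probe sets by 8 arrays. The deposited values were on a log2 scale, as their range of 1.92 to 14.66 shows. The quartiles were similar but not identical between arrays. Mutant arrays 1 and 2 had the highest lower quartiles (6.283 and 6.281, others 6.210 to 6.265). They also had the lowest upper quartiles (9.082 and 9.087, others 9.113 to 9.158). Whether and how arrays were normalized against each other is not stated. The submitters' processing notes name limma, without a version. The background correction, the summarization and normalization methods and the genome build were not given in the sources used here. A log2 table of summarized probe sets holds no background reading, so no probe set was called absent, and differences near the floor of the scale are compressed.

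Gene names came from the platform's annotation, updated through Entrez identifiers and RefSeq accessions to the gene table of the GRCm38.p6 assembly, which was used only for names and for which genes neighbour each other. Of the probe sets, 21789 named exactly 1 gene, 1621 named several and 12146 were not listed and stay unnamed. Of the 21789, 21701 matched a current gene and 88 kept the platform's symbol. For each gene the probe set with the highest mean over all 8 arrays was used, which left 19936 genes. No value was filtered, transformed or renormalized. No probe set carried the AFFX prefix of control probe sets, so removing these, as fixed beforehand, took out 0; some unlisted probe sets, 6617 of which have identifiers below the first listed one, can be array controls, and they remain in the counts over all probe sets. Because the array does not use the suffixes of older designs, a fit without probe sets ending in _s_at or _x_at, also fixed beforehand, would have removed 0 and was not run.

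Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 factor for the labelled group, all 8 arrays, two-sided), and adjusted by the Benjamini-Hochberg method over all genes, with calls at an adjusted p under 0.05. Every log2 difference is arrays labelled mutant minus arrays labelled control, and a fold is 2 to the size of that difference. Vhl was also tested by an exact permutation of the 4 against 4 values. The 27 gene lists of pathways and cell types were fixed before the data were examined, as were the main tests, and were tested with camera at a preset correlation of 0.01, adjusted over the lists. Members without a probe set naming them alone were left out. Camera with an estimated correlation and fry served as alternatives. Counts for these lists are given over all genes and adjusted over the list alone.

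The rule for named genes was also fixed beforehand. It took the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, Vhl, and from each list the 2 called members with the largest change, or the member with the largest change where none was called. Names that are only a clone or predicted-gene name were counted but not taken. Further members of lists with few called genes, and others said to be so, were chosen after their values were seen.

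The labels number the arrays 1 to 4 in both groups without saying that a number marks a shared litter or day. Deviations from the group means over genes correlated between same-numbered arrays at 0.138, 0.153, 0.295 and 0.175, all above 0.1. Among arrays of different numbers, mutant array 2 and control array 1 also passed 0.1, at 0.111. Each array correlated best with its own number, so the numbers were taken to pair the arrays. This pairing comes from the data and not from the labels. The fit without the block stayed the main test, as fixed beforehand, and the blocked value is given where it changes the call of a named gene, a list or a counted list member.

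The alternatives were quantile normalization, centring each array on its median, keeping the upper 60% of probe sets by mean, eBayes with trend and robust, array weights, the replicate block, the mean of a gene's probe sets, stricter thresholds, and leaving out each array in turn. Leaving out mutant arrays 1 and 2 together, or 3 and 4 together, and keeping only probe sets that the platform table names were added after the data were seen. The fits were tested on simulated data for the 19936 genes of this comparison with 200 genes changed. Of those changed by 0.5 on the log2 scale 83% were called, and of those changed by 1, 96%. Of 194 calls 10 were false. A list of 20 genes shifted by 0.3 had a camera p of 2.26e-28 and an unshifted list 0.938. The simulated genes were drawn independently of each other and without pairing. The simulation therefore does not test list calls where members are correlated, as in the macrophage list (estimated correlation 0.726).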

Results

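Whole-kidney RNA was measured on 8 Affymetrix mouse gene arrays. The labels assign 4 arrays to female mice carrying Pax8-rtTA, LC-1 and floxed Vhl alleles, here the arrays labelled mutant, and 4 to littermate controls, here the arrays labelled control. Pax8-rtTA with LC-1 is a doxycycline-inducible Cre system directed at kidney tubule epithelium, and Vhl encodes the von Hippel-Lindau protein, which marks the alpha subunits of hypoxia-inducible factor (HIF) for degradation. All mice drank doxycycline at 0.2 mg/ml in 5% sucrose for 2 weeks from the age of 3 weeks, had plain water for 1 week and were killed at 6 weeks. The deposited log2 values ran from 1.92 to 14.66, array medians lay between 7.55 and 7.58, and 19936 genes were tested. Correlations between arrays over these genes were 0.992 to 0.997 within a group and 0.987 to 0.993 between groups. Xist read 12.8 to 13.0 on every array and the Y-linked genes Eif2s3y, Kdm5d and Uty read 3.40 to 5.71; the labels give the mice as female. The number of arrays limits the precision of every value: the median standard error of a log2 difference was 0.0718.

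The comparison asked how deletion of Vhl in tubule cells changed kidney gene expression, and the targeted gene was read first. Vhl was not lower in the arrays labelled mutant. Its single probe set read 8.34 ± 0.0909 there (SD, n = 4) and 8.05 ± 0.118 in the arrays labelled control (SD, n = 4). This is 1.22-fold higher in the arrays labelled mutant (log2 difference 0.29, limma adjusted p = 0.0387, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 arrays allow). That permutation shuffled all 8 arrays freely and took no account of pairing by replicate number. The 4 labelled mutant arrays read 8.25, 8.32, 8.46 and 8.33, and the 4 labelled control arrays 8.01, 7.99, 7.96 and 8.22. The call was lost with the replicate number as a block (limma adjusted p = 0.0558). It was also lost without mutant array 2, 3 or 4 or control array 1, 2 or 3 (0.0858, 0.0868, 0.0785, 0.0995, 0.109 and 0.114), while over all alternatives the limma adjusted p ran from 0.0128 to 0.123. Which part of the transcript the probe set covers was not given in the sources used here, and a probe set outside the deleted part may miss the loss. Because the targeted gene and the HIF target genes both run against the labels, every direction below is between arrays labelled mutant and arrays labelled control and is not a direction of Vhl loss.

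Genes activated by HIF were lower in the arrays labelled mutant. Egln3, the prolyl hydroxylase whose transcript HIF induces, was 7.81-fold lower there (8.82 ± 0.229 against 11.8 ± 0.197, SD, n = 4 each). Car9, carbonic anhydrase 9, was 7.35-fold lower (7.18 ± 0.268 against 10.1 ± 0.696, SD, n = 4 each), with log2 differences of -2.96 for Egln3 and -2.88 for Car9. Adm, Pdk1 and Vegfa, which encode adrenomedullin, a kinase that inhibits pyruvate dehydrogenase and the vascular growth factor, were 3.44-fold, 3.02-fold and 1.79-fold lower. They were chosen after their values were seen. Of the 32 measured members of the HIF target list, 22 fell, 0 rose and 10 did not pass the test; adjusted over the list alone, 25 fell. With the replicate block the member Mxi1 did not pass (limma adjusted p = 0.0668). In all 22 the 4 labelled mutant arrays lay below the 4 labelled control arrays. The mean of the list was 9.43 ± 0.0372 in the arrays labelled mutant (range 9.37 to 9.46) and 10.2 ± 0.0942 in the arrays labelled control (range 10.1 to 10.3; SD, n = 4 each). Its median log2 change was -0.74 (camera adjusted p = 9.65e-28, and adjusted p = 0.0327 with an estimated correlation). Epo, which encodes erythropoietin, read 6.08 ± 0.263 against 5.92 ± 0.103 (SD, n = 4 each) and did not pass the test (limma adjusted p = 0.450). Both means lay below the lower quartile of every array (6.21 to 6.28), so a difference can be compressed there.

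**Figure D1:**
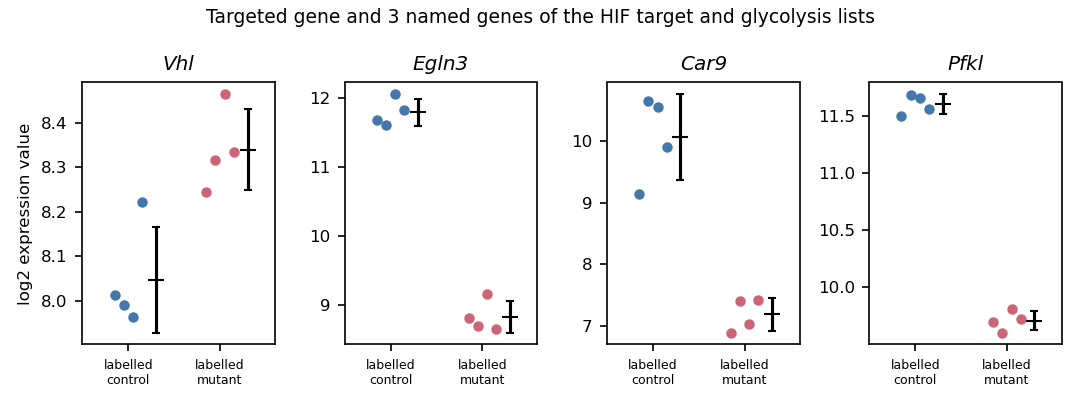
Log2 expression value (vertical axes, each panel with its own range) of Vhl, Egln3, Car9 and Pfkl on each of the 8 arrays; points are arrays, and the bar beside each group is its mean ± SD (n = 4). Vhl averages 8.34 in the arrays labelled mutant and 8.05 in those labelled control, whereas Egln3, Car9 and Pfkl lie lower in every array labelled mutant than in every array labelled control.

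Across all genes, 1442 of 19936 (7.23%) passed the limma test, of which 517 were higher and 925 lower in the arrays labelled mutant. Of these, 67 differed at least 2-fold, 10 higher and 57 lower. The largest fall was that of the defensin gene Defb19, 25.6-fold lower in the arrays labelled mutant (7.30 ± 0.138 against 12.0 ± 0.254, SD, n = 4 each; limma adjusted p = 7.64e-08). Next to Egln3 and Car9 came Mgarp, a mitochondrial protein gene (6.68-fold lower), Igfbp1, an insulin-like growth factor binding protein gene (6.58-fold), the mucin gene Muc2 (6.12-fold), Cyp2j13 (5.59-fold), the interleukin 17 receptor gene Il17rb (5.26-fold), the lactate exporter gene Slc16a3 (5.00-fold) and Alas2, the erythroid enzyme of haem synthesis (4.74-fold). The largest rises were smaller. The chemokine gene Ccl28 was 3.44-fold higher (9.99 ± 0.283 against 8.21 ± 0.605), the BMP antagonist gene Chrdl1 3.13-fold (8.94 ± 0.317 against 7.29 ± 0.485) and the nuclease gene Dnase1 3.06-fold (11.45 ± 0.444 against 9.84 ± 0.507; SD, n = 4 each). Hdc, the histidine decarboxylase gene, rose 2.71-fold, with mutant array 2 at 10.7 and the other mutant arrays at 8.73 to 9.28. Bcat1, a branched-chain aminotransferase gene, rose 2.63-fold, Cyp2d12 2.55-fold, Tm6sf2 2.32-fold, Sec14l3 2.18-fold and Ceacam2 2.17-fold. Pigr, the receptor that carries immunoglobulin A across epithelium, rose 2.08-fold. These 20 genes had log2 differences from -4.68 to 1.78 and limma adjusted p between 7.64e-08 and 0.0339.

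The 4 arrays of a group lay entirely on 1 side of the other group for 2944 genes (14.8%, where chance gives 2.86%), among them 1406 of the 1442. Among all 35556 probe sets 1580 passed, 369 higher and 1211 lower. The probe set count was 760 without control array 2, 776 without control array 3, 833 without mutant array 2, 925 without control array 1, 950 without mutant array 4 and 522 without mutant arrays 1 and 2. Over the probe sets that the platform table names, a choice made after the data were seen, it was 1976. The gene count was 917 without mutant array 2 (263 higher), 903 without control array 2 (284 higher) and 901 without control array 3 (282 higher). Quantile normalization gave 697 higher and 878 lower genes, and over all alternatives at the same threshold the share higher ran from 28.7% to 44.3%, against 35.9% of the 1442. Hdc lost its call without mutant array 1 or 3 or any 1 of the 4 control arrays (limma adjusted p from 0.0513 to 0.0956), and Ceacam2 without mutant array 2, 3 or 4 (0.0526 to 0.0673). On the first principal component (43.8% of the variance) the 4 labelled mutant arrays lay between -19.6 and -8.83 and the labelled control arrays between 9.71 and 20.3. The next component (19.1%) set mutant arrays 1 and 2 (14.5 and 6.99) apart from mutant arrays 3 and 4 (-16.3 and -14.2). Over all probe sets the first component (35.3%) placed mutant arrays 1 and 2 at -34.5 and -34.4, mutant arrays 3 and 4 at 1.03 and -4.58 and the control arrays at 11.9 to 29.1, so mutant arrays 3 and 4 lay nearer to the control mean than to mutant arrays 1 and 2.

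**Figure D2:**
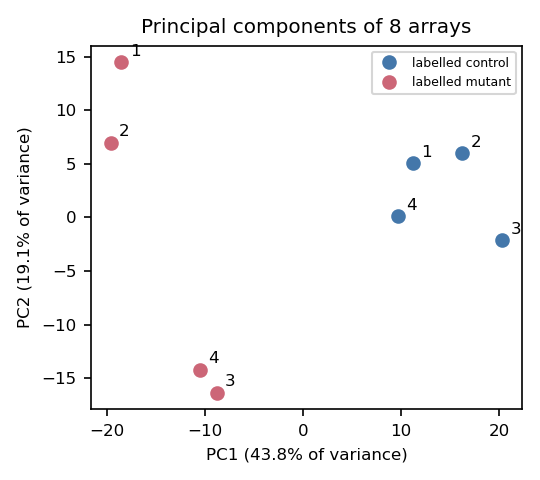
Principal components of the 8 arrays over the 19936 genes, first component (43.8% of the variance) against the next (19.1%); each point is an array, numbered by its replicate, and colour gives the labelled group. The labelled groups separate on the horizontal axis, and mutant arrays 1 and 2 lie above mutant arrays 3 and 4 on the vertical axis.

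Glycolytic genes were lower in the arrays labelled mutant as well. Pfkl, a phosphofructokinase gene, was 3.72-fold lower (9.71 ± 0.0844 against 11.6 ± 0.0871, SD, n = 4 each), and Slc16a3 fell from 10.2 ± 0.171 to 7.92 ± 0.210 (SD, n = 4 each). Hk2, Ldha and Pgk1, which encode a hexokinase, lactate dehydrogenase and phosphoglycerate kinase, were 2.42-fold, 1.94-fold and 1.72-fold lower; they were chosen after their values were seen. Of the 16 measured members 13 fell, Pfkm, the muscle-type phosphofructokinase gene, rose (log2 difference 0.24), and 2 did not pass; adjusted over the list alone the counts were 13 and 1. The median log2 change was -0.74 (camera adjusted p = 1.20e-20, and adjusted p = 0.0327 with an estimated correlation). Slc2a1, the glucose transporter gene, is in this list and in that of HIF targets.

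Few genes of mitochondrial metabolism passed the test. Ndufa4, a respiratory chain subunit gene, was 1.45-fold higher in the arrays labelled mutant (11.1 ± 0.0289 against 10.6 ± 0.136, SD, n = 4 each). Uqcrq, of complex III, was 1.19-fold and Sdhb, of succinate dehydrogenase, 1.22-fold higher. In the oxidative phosphorylation list 2 of 32 measured members rose and 0 fell (1 and 0 adjusted over the list alone), with a median log2 change of 0.08 (camera adjusted p = 0.00145, but adjusted p = 0.307 with an estimated correlation; median 0.12 after quantile normalization). In the citric acid cycle list 1 of 16 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.00959, but adjusted p = 0.267 with an estimated correlation). With the replicate block Uqcrq no longer passed (limma adjusted p = 0.0504) and Ndufs4 did (0.0380). Uqcrq also lost its call without any 1 of the 4 mutant arrays or control array 1, 2 or 3 (0.0691 to 0.131), Sdhb without any 1 of the 4 mutant arrays or control array 2, 3 or 4 (0.0546 to 0.128), and the citric acid cycle list without mutant array 3 (0.0681).

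Pdk4, whose kinase restrains pyruvate oxidation, was 3.08-fold lower in the arrays labelled mutant (10.5 ± 0.469 against 12.1 ± 0.420, SD, n = 4 each), and the thioesterase genes Acot1 and Acot2 were 1.73-fold and 1.46-fold lower. These were the 3 of 23 measured fatty acid oxidation genes that fell, and 0 rose; adjusted over the list alone 4 fell and 2 rose. The list's median was -0.11 (camera adjusted p = 0.00637, but adjusted p = 0.520 with an estimated correlation, and 0.0744 without mutant array 1). Its median was -0.06 without mutant array 1, -0.07 without control array 2, -0.06 after quantile normalization, -0.02 without mutant arrays 1 and 2 and -0.20 without mutant arrays 3 and 4. Acot1 did not pass without mutant array 1 or 2 or control array 1, 2 or 4 (limma adjusted p from 0.0645 to 0.0859). Pcx, pyruvate carboxylase, and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, fell 1.37-fold and 1.36-fold. They were the 2 of 7 gluconeogenesis genes that passed, by either adjustment, and the list had a median of -0.17 (camera adjusted p = 0.0197, but adjusted p = 0.317 with an estimated correlation, 0.156 without mutant array 1, 0.0975 after quantile normalization and 0.0668 with the upper 60% of probe sets by mean). Lpl, lipoprotein lipase, and Fabp3 were higher by log2 differences of 0.67 and 0.59, while Fabp4, Plin2, Vldlr, Hilpda and Plin5 were 1.61-fold, 1.58-fold, 1.49-fold, 1.46-fold and 1.26-fold lower. These 2 higher and 5 lower genes of the 15 in the lipid storage and uptake list (3 and 6 adjusted over the list alone) left a median of -0.12, and the list was not called (camera adjusted p = 0.0586, though 0.0101 without mutant array 4 and 0.0457 without control array 4). The median was -0.20 and -0.21 without these, -0.07 without mutant array 1 (0.171) and -0.06 without mutant array 3 (0.0625). Of 12 iron handling genes 3 fell by either adjustment: Hmox1, haem oxygenase 1 (2.32-fold lower), Tfrc, the transferrin receptor (1.87-fold), and Slc11a2, an iron importer (1.76-fold). That list was not called either (median -0.09, camera adjusted p = 0.0736, though 0.0352 without mutant array 4 and 0.0401 without control array 4). Its median turned to 0.03 without mutant array 1 (0.229) and 0.04 without mutant arrays 1 and 2 (0.506). Hmox1 did not pass without mutant array 1, 2 or 3 or control array 3 (limma adjusted p from 0.0643 to 0.0906).

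Endothelial genes were lower together in the arrays labelled mutant. Kdr, the main VEGF receptor gene, was 1.86-fold lower (9.21 ± 0.173 against 10.1 ± 0.203, SD, n = 4 each) and Cdh5, VE-cadherin, 1.79-fold lower (10.003 ± 0.0765 against 10.8 ± 0.142, SD, n = 4 each). Of the 15 endothelial markers 13 fell, 0 rose, and Plat and Cldn5 did not pass; adjusted over the list alone 14 fell. The median log2 change was -0.64 (camera adjusted p = 3.72e-21, and adjusted p = 0.0327 with an estimated correlation). Among 10 measured perivascular and renin cell genes 6 fell and 0 rose (9 and 0 adjusted over the list alone). They included the contractile genes Cnn1 (1.81-fold lower) and Acta2 (1.62-fold), and the list's median was -0.40 (camera adjusted p = 2.78e-08, but adjusted p = 0.184 with an estimated correlation). The list's Ren1 and Akr1b7 had no probe set naming them alone, so the list does not read renin cells. In the fibroblast and matrix list 5 of 16 measured genes fell and 1 rose (6 and 1 adjusted over the list alone). The matrix proteoglycan genes Lum and Dcn fell 2.06-fold and 1.55-fold, the collagen cross-linking enzyme gene Lox 1.67-fold, Sparc 1.52-fold and Tgfb1 1.35-fold, and Tgfb2 rose 1.42-fold. That list had a median of -0.13 (camera adjusted p = 0.00637, but adjusted p = 0.317 with an estimated correlation). Lox did not pass without any 1 of mutant arrays 1, 2 and 3 or of the 4 control arrays (limma adjusted p from 0.0512 to 0.0897).

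Proliferation genes were also lower in the arrays labelled mutant. Mki67, a marker of cycling cells, was 1.98-fold lower (7.48 ± 0.348 against 8.46 ± 0.247, SD, n = 4 each) and the cyclin gene Ccna2 1.80-fold lower (7.55 ± 0.247 against 8.40 ± 0.156, SD, n = 4 each). Of 21 measured members 15 fell, 0 rose and 6 did not pass; adjusted over the list alone 18 fell and 1 rose. The median was -0.42 (camera adjusted p = 4.64e-14, but adjusted p = 0.129 with an estimated correlation). With the replicate block the members Plk1, Mcm5 and Mcm6 did not pass (limma adjusted p = 0.0652, 0.0517 and 0.0617). In the tubular injury list Clu, clusterin, rose 1.70-fold (11.1 ± 0.161 against 10.3 ± 0.0715, SD, n = 4 each), and the cytoskeletal genes Krt19 and Vim fell 2.34-fold and 1.33-fold. These 3 were the members of 13 measured that passed by either adjustment, and the list was not called (median -0.09, camera adjusted p = 0.346).

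In the proximal tubule list the organic anion transporter gene Slc22a7 was 1.91-fold higher in the arrays labelled mutant (11.007 ± 0.179 against 10.1 ± 0.404, SD, n = 4 each) and the neutral amino acid transporter gene Slc6a19 1.76-fold higher (11.4 ± 0.155 against 10.6 ± 0.251, SD, n = 4 each). Of its 28 genes 7 rose, 1, the bicarbonate cotransporter gene Slc4a4, fell 1.16-fold, and 20 did not pass; adjusted over the list alone 8 rose and 1 fell. Its median was 0.12 (camera adjusted p = 0.00637, but adjusted p = 0.383 with an estimated correlation, and 0.0625 without mutant array 3). In the thin limb and thick ascending limb list Cldn19 and Cldn16, tight junction genes of magnesium reabsorption, rose 1.57-fold and 1.42-fold, and Casr and Kcnj1 both 1.25-fold. These were the 4 of 15 measured members that passed (10 adjusted over the list alone) and 0 fell, with a median of 0.24 (camera adjusted p = 1.05e-05, but adjusted p = 0.136 with an estimated correlation). Of 10 measured genes of the distal convoluted and connecting tubule 5 rose and 0 fell (7 and 0 adjusted over the list alone). They were S100g, a calcium-binding protein gene (1.87-fold), the magnesium channel gene Trpm6 (1.64-fold), Calb1 (1.45-fold), Klhl3 (1.31-fold) and Cnnm2 (1.24-fold), and the list's median was 0.35 (camera adjusted p = 0.000114, but adjusted p = 0.225 with an estimated correlation). With the replicate block Slc12a1 and Enox1 of the thick limb list (limma adjusted p = 0.0456 and 0.0496) and Slc12a3 and Slc8a1 of the distal list (0.0341 and 0.0275) passed as well.

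In the collecting duct, the ammonia transporter gene Rhbg rose by 0.68 on the log2 scale, the water channel gene Aqp3 by 0.45 and Hsd11b2 by 0.31 in the arrays labelled mutant. These were the 3 of 11 principal cell genes that passed (5 adjusted over the list alone) and 0 fell, with a median of 0.21 (camera adjusted p = 0.00637, but adjusted p = 0.267 with an estimated correlation). Of 12 intercalated cell genes 3 rose and 0 fell (4 and 1 adjusted over the list alone): the proton pump subunit genes Atp6v1c2 and Atp6v1b1 (1.37-fold and 1.26-fold) and the anion exchanger gene Slc4a9 (1.30-fold). That list's median was 0.15 (camera adjusted p = 0.0405, but adjusted p = 0.512 with an estimated correlation), and its call was lost without mutant array 2, 3 or 4 or control array 1, 3 or 4 (0.0567 to 0.133). Aqp3 did not pass without mutant array 1, 2 or 4 or control array 1, 2 or 3 (limma adjusted p from 0.05002 to 0.106), nor Slc4a9 without mutant array 2, 3 or 4 or control array 1, 3 or 4 (0.0658 to 0.109).

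**Figure D3:**
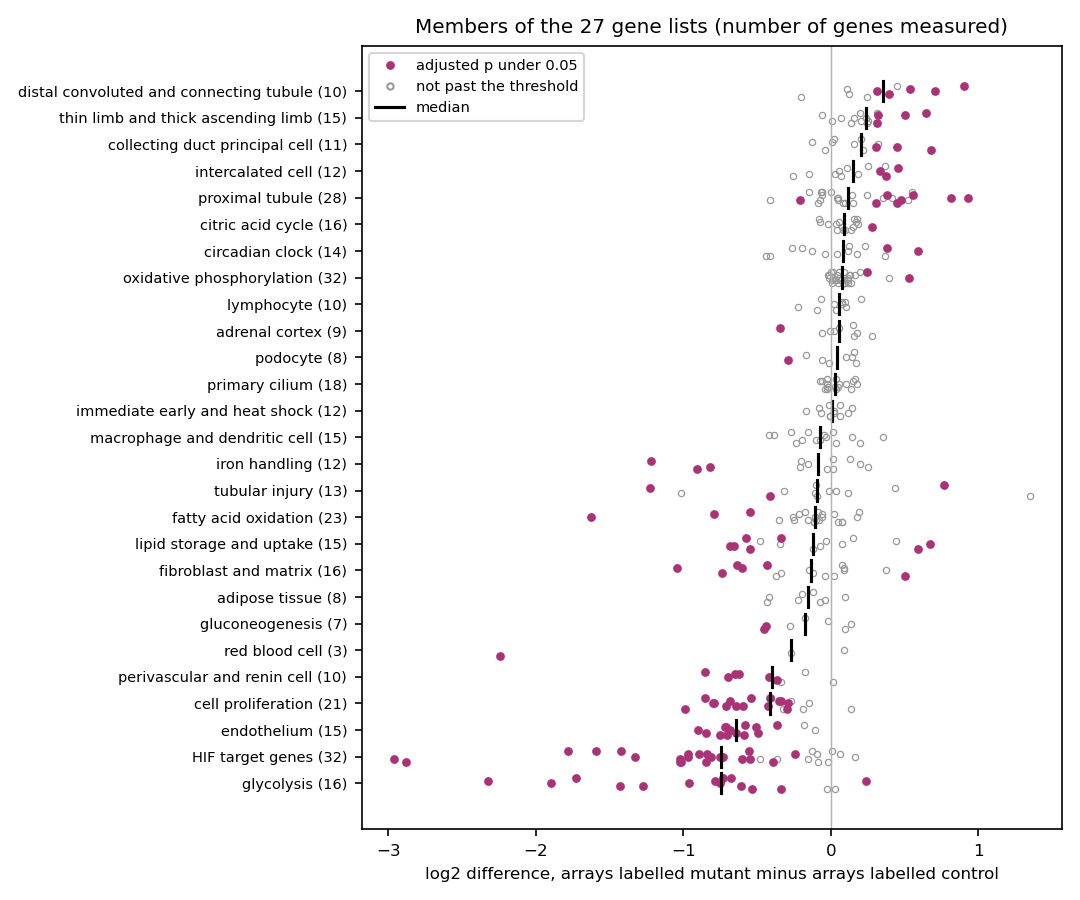
Log2 difference, arrays labelled mutant minus arrays labelled control (horizontal axis), for each measured member of the 27 gene lists (vertical axis, with the number of genes measured); filled points passed the limma test, open points did not, and the bar is the list's median. Glycolysis, HIF target and endothelial genes lie lowest, with medians of -0.74, -0.74 and -0.64, and distal convoluted and connecting tubule genes highest, with a median of 0.35.

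Markers of other cell types were read in the same way. Of 8 measured podocyte genes Podxl fell 1.22-fold in the arrays labelled mutant (11.5 ± 0.0337 against 11.8 ± 0.0738, SD, n = 4 each), 0 rose by either adjustment, and the list was not called (median 0.04, camera adjusted p = 0.848). Of 15 macrophage and dendritic cell genes and 10 measured lymphocyte genes 0 passed by either adjustment (camera adjusted p = 0.179 and 0.764, medians -0.07 and 0.06). Itgam, an integrin gene of myeloid cells, had a log2 difference of -0.42 (limma adjusted p = 0.0530) and passed with the replicate block (0.0148), quantile normalization (0.0326), median centring (0.0462), eBayes with trend and robust (0.0420) and array weights (0.0223). It also passed without mutant array 2 (0.0461), without control array 4 (0.0303) and without mutant arrays 1 and 2 (limma adjusted p = 0.0196). Cd3g, of the T cell receptor complex, had a log2 difference of -0.22 (limma adjusted p = 0.507, and 0.0388 without mutant arrays 1 and 2). The mean of the macrophage list was 8.729, 8.542, 7.9995 and 8.018 in mutant arrays 1 to 4 and 8.413, 8.513, 8.436 and 8.237 in control arrays 1 to 4. Without mutant arrays 1 and 2, left out together after the data were seen, its median was -0.39 (camera adjusted p = 1.85e-09). It was also called with array weights on all 8 arrays (median -0.18, camera adjusted p = 0.0296), and without mutant array 1 (0.00341), mutant array 2 (0.0431) or control array 4 (0.0372). Without mutant array 3 or 4 its median turned to 0.04 or 0.02 (0.771 and 0.621), and without both to 0.16 (0.0511). Cd68, a macrophage marker, passed with the replicate block (limma adjusted p = 0.0334).

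Of 3 measured red blood cell genes Alas2 fell, and 2 fell adjusted over the list alone. The list had a median of -0.27 (camera adjusted p = 0.0405, but adjusted p = 0.267 with an estimated correlation, 0.0681 without mutant array 3 and 0.0773 without mutant array 4). The median was -0.18 without control array 2 and, with the upper 60% of probe sets by mean, -2.24, the value of Alas2. Its other 8 genes, the globin genes among them, had no probe set naming them alone. Fdx1, a mitochondrial ferredoxin gene, fell 1.27-fold as the only member of the 9-gene adrenal cortex list to pass by either adjustment (median 0.06, camera adjusted p = 0.571). Of 8 measured adipose tissue genes 0 passed by either adjustment (median -0.16, and -0.01 without mutant arrays 1 and 2; camera adjusted p = 0.179). That list was called without mutant array 4 (0.0311) or control array 4 (0.0327), and Adipoq, which encodes adiponectin, had a log2 difference of -0.43 (limma adjusted p = 0.330). The clock output genes Dbp and Tef rose 1.51-fold and 1.30-fold, the only 2 of 14 measured circadian clock genes to pass by either adjustment (median 0.08, camera adjusted p = 0.569). Dbp did not pass without mutant array 1 or 2 or control array 2, 3 or 4 (limma adjusted p from 0.0761 to 0.109), nor Tef without mutant array 2 or 4 or control array 2, 3 or 4 (0.0595 to 0.0800), and with the replicate block Cry1 and Nr1d1 passed (0.0288 and 0.0324). Of 18 measured primary cilium genes and 12 measured immediate early and heat shock genes 0 passed by either adjustment (camera adjusted p = 0.565 and 0.935), and the largest differences were those of Ift27 (log2 0.18, limma adjusted p = 0.285) and Ier3 (log2 -0.17, limma adjusted p = 0.389). The cilium list had a median of 0.03 and the immediate early list a median of 0.01, the latter opposite in sign to the direction camera gave it.

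Among the 27 lists camera called 16, of which 7 were higher and 9 lower in the arrays labelled mutant. With an estimated correlation 3 were called: HIF target genes, glycolysis and endothelium. Without mutant arrays 1 and 2 the fatty acid oxidation and gluconeogenesis lists were no longer called (camera adjusted p = 0.388 and 0.321; medians -0.02 and -0.10), and the citric acid cycle median was 0.15. Without mutant arrays 3 and 4 the oxidative phosphorylation, citric acid cycle, proximal tubule, intercalated cell and red blood cell lists were not called (0.164, 0.319, 0.255, 0.379 and 0.214; medians 0.05, 0.06, 0.08, 0.10 and -0.26), whereas lipid storage and uptake (0.00966) and iron handling (0.0317) were. By fry, which does not compare a list with other genes, fatty acid oxidation and intercalated cell genes were not called (0.271 and 0.131) and iron handling genes were (0.0213). Of the genes named by the rule, Krt19, Hmox1, Cnn1, Acot1, Lox, Fabp4, Podxl, Uqcrq, Sdhb, Tef, Aqp3, Dbp, S100g, Slc22a7 and Bcat1 also did not pass without mutant arrays 1 and 2 (limma adjusted p from 0.0623 to 0.234). Uqcrq, Sdhb, Slc4a9, Ceacam2 and Sec14l3 did not pass without mutant arrays 3 and 4 (0.0671 to 0.132). Hmox1, Ceacam2 and Hdc did not pass in the limma fit with trend and robust (0.0822, 0.0645 and 0.0975), nor Sdhb and Dbp with array weights (0.0593 and 0.0798).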

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

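The tests in this part that weigh an explanation, including the counts over other splits of the arrays, were written after the results they bear on had been seen.

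Among the named genes, an array stood far from the other 3 of its group in 5 of 124 groups, where chance gives about 1 in 20. The ratio of the gap to the group's range was 0.841 for Acta2 in control array 4 (11.1 against 11.2 to 11.3), 0.843 for Aqp3 in control array 3 (9.58 against 9.94 to 10.01), and 0.945 for Ceacam2 in mutant array 1 (12.1 against 12.8). It was 0.923 for Cyp2j13 in mutant array 3 (8.04 against 7.34 to 7.39) and 0.875 for Ift27 in mutant array 2 (7.69 against 7.49 to 7.51).

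The HIF target genes and Vhl run against the group labels, and a candidate explanation is that the labels of the 2 groups are exchanged as a whole, since the mean of the HIF target list differed by -0.79 between the labelled groups with Vhl higher where the label says it was deleted. A single wrong label or a crossed pair is argued against, because 0 of the 8 arrays lay on the side of the midpoint of that mean that its label names. Normalization between arrays is argued against too, because the list's median stayed at -0.71 after quantile normalization. Median centring gave -0.74 but tests little, since the array medians already lay between 7.55 and 7.58. That the labels are right and HIF target genes fall after Vhl loss cannot be told apart from an exchange by Vhl itself, whose difference of 0.29 decides only if its probe set reads the deletion. The HIF target list argues against right labels, because the Vhl protein marks HIF alpha subunits for degradation, so its loss should raise these genes. Of the 32 measured members 22 were lower in the arrays labelled mutant, 0 were higher and 10 did not pass. In all 22 the labelled groups did not overlap. The labels alone do not settle which group lacked Vhl, and they were kept as deposited.

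The count of 1442 genes was matched by 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, and the highest other split gave 1 gene. The share of 1 in 35 counts against chance only if the arrays are not paired and all 35 splits count alike. Each other split mixes the labelled groups, which widens the spread within its groups, so its low count is partly built in. For probe sets the real split gave 1580 and the highest other 2, again 1 of 35. For the gene lists 1 of 35 splits also gave as many as the real 16, but the highest other gave 15 and the median of the others was 7. Where the numbers pair the arrays, as the correlations in the data were read, only the 8 splits that part all 4 pairs compare with the real one, too few for a share under 0.05; the highest other of these gave 0 genes and 15 lists, and the other splits keep 2 or 4 pairs together.

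The 13 endothelial genes that fell may reflect a smaller endothelial share in the kidneys labelled mutant or lower expression per cell, which bulk RNA does not separate. A lower share of tubule cells in the kidneys labelled control would raise markers of every other cell type alike there. The median of the podocyte and macrophage lists together (23 genes) lay 0.595 above that of the endothelial list, where the members of the latter had an SD of 0.225 (two-sided permutation p = 1e-05, the smallest that 100000 resamples give). Because the macrophage list varied among the arrays labelled mutant, the 8 podocyte genes were then tested alone, and their median lay 0.686 above (two-sided exact permutation p = 0.000245). Both permutations shuffled correlated genes, so their p do not measure the spread between mice. Perivascular and fibroblast lists were lower (medians -0.40 and -0.13) and tubule and collecting duct lists higher (0.12 to 0.35), as that explanation predicts. Over single arrays left out the podocyte median ran from 0.0167 to 0.0978 and the endothelial median from -0.664 to -0.594. This gap argues against that explanation as the whole cause. Nor do mutant arrays 1 and 2 account for the endothelial fall, since without them the camera adjusted p of the endothelial list was 2.45e-18.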

How the results depend on the processing

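Leaving out 2 mutant arrays together and keeping only named probe sets were chosen after the data were seen. The causes of the changes below were not tested, though a stricter threshold can only lower a count. Fewer arrays did not always lower it: without mutant arrays 3 and 4 the gene count was 1562, against 1442 with all arrays. Vhl kept its direction under every alternative run (limma adjusted p from 0.0128 to 0.123), with log2 differences of 0.29 with the replicate block (not called), 0.25 to 0.35 over the arrays left out in turn, 0.35 without mutant arrays 1 and 2 and 0.23 without 3 and 4, not called in the last 2. The gene count ran from 901 to 1368 over single arrays left out, with 602 genes at an adjusted p under 0.01 and 67 at 2-fold. The probe set count ran from 760 to 1278, with 522 without mutant arrays 1 and 2, 418 at 0.01 and 78 at 2-fold, and was lowest without control arrays 2 (760) and 3 (776), mutant arrays 2 (833) and 4 (950) and control array 1 (925). The replicate block gave 1657 genes, 1281 of them shared, and among the genes named by the rule and the lists as wholes it changed only the calls of Vhl, Uqcrq and Itgam; estimated correlation called 3 lists and fry 15. Among lists that were not called, the direction given by camera or the sign of the median turned under the settings that follow. Without mutant arrays 3 and 4 the medians were 0.0288 (podocyte), 0.162 (macrophage), 0.0725 (tubular injury), -0.0220 (cilium), -0.0237 (immediate early) and 0.0428 (clock), and Cd3g had 0.0971. Without mutant arrays 1 and 2 they were -0.116 (lymphocyte), 0.0370 (iron handling), -0.0179 (adrenal) and 0.0193 (immediate early). Quantile normalization gave 0.0421 and array weights 0.00489 (lymphocyte), the upper 60% -0.161 (adrenal) and 0.00739 (immediate early), and for the latter array weights 0.0317 and fry 0.00841. Over the single arrays left out the medians of lists not called ran from 0.0167 to 0.0978 (podocyte), -0.0560 to 0.125 (lymphocyte), -0.00920 to 0.0495 (cilium), 0.0374 to 0.0982 (clock), -0.122 to 0.0325 (iron handling), -0.213 to 0.0366 (macrophage), -0.156 to -0.0207 (tubular injury), -0.234 to -0.0511 (adipose), 0.0159 to 0.0980 (adrenal) and -0.0441 to 0.0699 (immediate early). Over the genes named by the rule other than Vhl, and all alternatives, 937 values kept the direction of the test and their side of the threshold, 87 lost a call, 9 gained one and 1 turned; for lists the counts were 438, 36, 14 and 25, and those that turned were past the threshold in neither direction. Values near the floor of the log2 scale limit what low genes can show.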

Other observations

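All tests in this part were chosen after the data were seen.

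The genes of the HIF subunits did not move together. Hif1a was 1.51-fold higher in the arrays labelled mutant (11.3 ± 0.0976 against 10.7 ± 0.213, SD, n = 4 each; limma adjusted p = 0.00660), whereas Epas1, which encodes HIF-2 alpha, was 1.29-fold lower (11.6 ± 0.0304 against 12.0 ± 0.113; limma adjusted p = 0.00660). Hif3a was 2.91-fold lower (7.59 ± 0.523 against 9.13 ± 0.180; limma adjusted p = 0.00304), and Arnt, their partner, had a log2 difference of 0.09 (limma adjusted p = 0.391). Genes of the basement membrane and collagen processing were lower in the arrays labelled mutant: 9 of 13 fell and 0 rose by either adjustment, with a median log2 change of -0.45 (camera adjusted p = 2.14e-11, but adjusted p = 0.0572 with an estimated correlation). Of 11 endothelial tip cell genes 6 fell, Flt4, Dll4, Apln, Nid2, Aplnr and Kcne3, and 0 rose; adjusted over the list alone 6 fell and 1 rose (median -0.50, camera adjusted p = 6.98e-06, but adjusted p = 0.144 with an estimated correlation). Apln is also in the HIF target list.

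Among 14 measured genes of cholesterol synthesis and uptake Msmo1, Insig1 and Idi1 rose in the arrays labelled mutant and 0 fell; adjusted over the list alone 7 rose and 0 fell (median 0.20, camera adjusted p = 0.000102, but adjusted p = 0.219 with an estimated correlation). Of 17 measured interferon-stimulated genes 3 fell and 0 rose, and 5 fell and 0 rose adjusted over the list alone (median -0.18, camera adjusted p = 0.000135, but adjusted p = 0.280 with an estimated correlation). The adjusted p of these 4 lists were taken over the 4 lists alone.

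Havcr1, which encodes the injury marker KIM-1, took 2 levels that did not follow the labelled groups. It read 10.7, 10.9, 6.25 and 10.1 in mutant arrays 1 to 4 and 10.2, 6.56, 6.56 and 9.25 in control arrays 1 to 4. Jchain, a gene of antibody-secreting cells, read 7.28 and 8.60 in mutant arrays 1 and 2 and 5.38 to 5.98 on the other 6 arrays, and the complement gene C4b read 10.3 and 8.79 there and 7.54 to 8.01 elsewhere. Ugt2b38 read 10.1, 9.11 and 9.27 in mutant arrays 1, 2 and 4, and 6.83 in mutant array 3, where the control arrays read 6.72 to 7.01. Ugt2b37 read 9.88 in mutant array 1 and 7.04 to 7.31 on the other 7.

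Flanking DNA of the floxed allele, where it comes from another strain, may make genes near Vhl differ between littermates. Of the 30 measured genes nearest to Vhl in gene order 2 were called, Il17re and Vgll4 (6.67%, against 7.23% of all other genes, two-sided Fisher's exact p = 1). No excess was seen around Vhl, but 30 genes can show only a large one. The test also cannot decide the point if both labelled groups carried the floxed allele.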
